A study of Mus musculus with 15 samples.

How the data were processed

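Gene expression was measured in 15 mouse samples with Affymetrix Mouse Genome arrays, 3 for each of 5 groups of cells. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was prepared from 5 µg of it. The deposited table holds log2 expression values for 45101 probe sets, which the authors made by robust multi-array average (RMA), a procedure that corrects for background, normalises arrays to shared quantiles and summarises the probes of a set. The processing notes name RMA without a version. The log base is not stated and was taken as 2 from the range of the values, of which the lowest is 1.32. Arrays carry no read depth, and their number limits the precision.

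Of the probe sets, 64 are controls, 34945 carried exactly 1 gene symbol in the annotation of the array, 932 carried several and 9160 carried none. The gene IDs of 34741 matched the RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. No genome build is named for the array table, so no coordinates are given. The probe set with the highest mean over all arrays stood for each gene, which left 18193 genes, of which 9010 had more than 1 probe set. Probe sets without a symbol or with several were left out of the tests.

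A model of the 5 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with 10 residual degrees of freedom. For 7 comparisons of pairs of groups, p was two-sided and adjusted by the Benjamini-Hochberg method over all genes. A gene was said to have risen, fallen or changed at an adjusted p under 0.05 and a fold of at least 2. Errors given with a log2 change are standard errors (SE) from this model and therefore pool the spread of all 5 groups. Errors of group means are SD with n = 3. The moderated F test over the 5 groups used no fold limit. The difference between the changes on return, MLC minus Hepatocyte and dHD28 minus HD28, was tested as a contrast of the same model with the same thresholds. The labels do not say that a replicate number marks a shared animal, batch or day. Between HD28 and dHD28 the deviations from the group means correlated in each of the 3 same-number pairs (0.32, 0.28 and 0.12), so the numbers may pair these samples. Arrays of the same number there also share the spike-in class, so the number cannot be told apart from it. Between dHD28 and MLC, which enter the difference between the changes on return, the pairs had 0.21, 0.78 and 0.6, with pair 1 of unlike class. In each other comparison of 2 groups at least 1 pair was under 0.1.

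The position of an array between MSC and Hepatocyte is a least squares projection over the genes that changed between those groups, with 0 at the MSC mean and 1 at the Hepatocyte mean. Positions were compared by exact two-sided permutation tests, in which 3 arrays against 3 cannot give a p below 0.1. Overlaps of gene sets were set beside the number that independent sets would share and beside 100 simulations in which the groups did not differ but shared arrays as in the study.

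The comparisons, the tests, 37 gene lists, the alternatives other than those named below and the rule for named genes were fixed before the data were examined. Of 765 list members, 696 had a named probe set. For each list the members that changed were counted after adjustment over all genes and adjusted over the list alone. Camera in limma compared a list with all other genes, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, and fry tested a list by itself. List p-values were adjusted over the lists. Genes are named by a rule: the 5 highest and 5 lowest log2 changes in a comparison among genes whose arrays did not overlap between the groups, without symbols that are clone or model identifiers; for each list described, the 4 changed members with the largest change, or the 2 largest where none changed; and any member of the list of DNA methylation genes. The rule gives more genes than are named. Col1a1 and Fkbp5 as level controls for an array, and Apoa1 and Cyp4a14 as examples for it, were chosen after their values were seen.

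The alternatives were other treatments of probe sets of a gene, removal of dim or cross-hybridising probe sets, quantile normalization of the table again, centring of each array on its median or on housekeeping genes, trend and robust options, fits with only the arrays compared, array weights, no fold limit, a treat test against a fold of 1.5, the replicate number as a block, and each array left out in turn. After the data were examined, 3 were added: the class of the poly-A spike-in signal as a block, that block with HD28 replicate 3 left out, and only arrays of low spike-in signal. The model was tested on simulated data with the spread of each gene in these arrays. Values were drawn independently, without structure shared by genes of an array. Per comparison 100 of 18193 genes changed by 1 log2 unit and another 100 by 2 log2 units. Of genes changed by 2 log2 units it called 92 between dHD28 and MSC and 90 between MLC and MSC. Of genes changed by 1 log2 unit it called 31 and 39. Figures were drawn with matplotlib 3.10.9.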

Results

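The samples trace a path from mesenchymal stromal cells (MSC) toward a hepatocyte-like state and back. Mouse MSC were grown in low-glucose medium with 10% serum. HD28 cells are MSC given hepatocyte growth factor at 20 ng/ml, basic fibroblast growth factor at 10 ng/ml and nicotinamide for 7 days, then oncostatin M at 20 ng/ml and the glucocorticoid dexamethasone at 1 µmol/L. Cells named dHD28 are HD28 cells returned to MSC medium. Primary hepatocytes formed the reference group (Hepatocyte). By the labels, MLC are hepatocytes kept in MSC medium with TGF-β1, lowered from 10 to 5 and then 1 ng/ml up to day 28. The series title concerns the part of DNA methyltransferases in the reversibility of this differentiation. Each group had 3 arrays, with array medians between 4.84 and 4.95 on the log2 scale. The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between samples. Among the 5 groups, 8508 of 18193 genes differed by the F test (46.8%). The table holds no detection calls. In 56 of 239 changes weighed for naming, the dimmer mean lay under the lower quartile of its arrays (3.43 to 3.7). Such a gene need not be above background, so the size and rank of its change are approximate.

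The arrays fell into classes of poly-A spike-in signal, a control added to the RNA before labelling. It was high (7.61 to 8.73) in 6 arrays and low (4.87 to 5.61) in 9, and each group held both classes. Gene expression differed between the classes as well. At an adjusted p under 0.05 and a fold of at least 2, 397 genes were lower and 6 higher in the high class. Among the lower genes are some named below, such as Mmp13 (log2 -3.03), Dcn (-1.91) and Osmr (-1.23). Standard errors from fits without the class as a block include this difference. HD28 replicate 3 differed from the other HD28 arrays in hepatocyte genes. Albumin (Alb) stood at 13.8 in it, at 3.38 and 3.74 in HD28 replicates 1 and 2, and at 14.12 ± 0.02 in the hepatocytes. The Kupffer cell gene C1qb stood at 4.98 against 2.83 and 2.87, whereas the collagen gene Col1a1, at 13.17, and the glucocorticoid target Fkbp5, at 11.53, were within 0.5 log2 units of the other HD28 arrays. The 3' to 5' difference of actin probes, a measure of RNA quality, was 0.94 in this array and 0.29 and 0.23 in the others. Lists of hepatocyte genes in HD28 are therefore also given without this array.

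**Figure D1:**
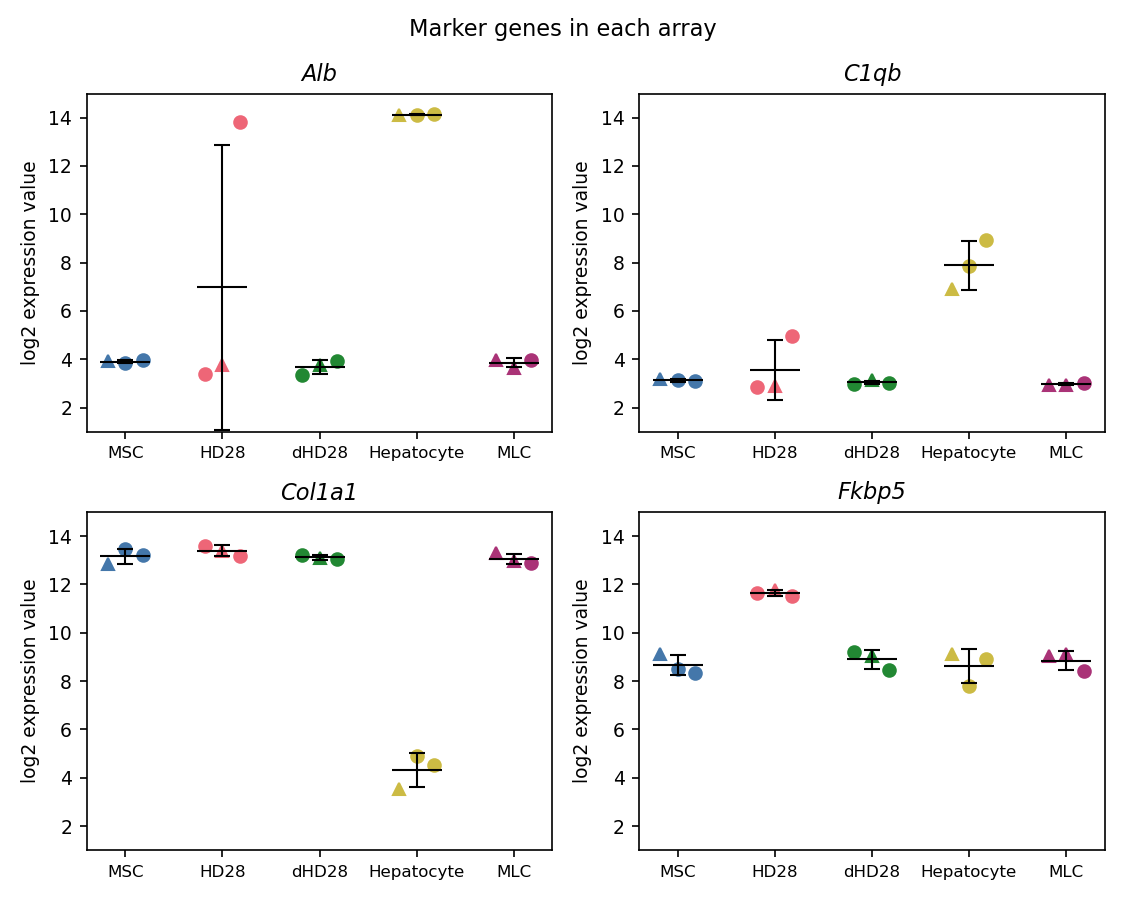
Log2 expression of Alb, C1qb, Col1a1 and Fkbp5 in each array (circles, low spike-in class; triangles, high), with group mean and SD (n = 3). Alb is at 13.8 in HD28 replicate 3 and at 3.38 and 3.74 in the other HD28 arrays.

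On the axis from MSC at 0 to Hepatocyte at 1, HD28 lay at 0.20 ± 0.18 (SD, n = 3), with arrays at 0.0763, 0.124 and 0.401. Without HD28 replicate 3 the mean was 0.0999. The dHD28 arrays lay at -0.004 ± 0.0097 (0.0124 without MSC replicate 1) and the MLC arrays at -0.0052 ± 0.023. HD28 differed from MSC and from dHD28 with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows, and MLC from MSC with p = 0.7.

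**Figure D2:**
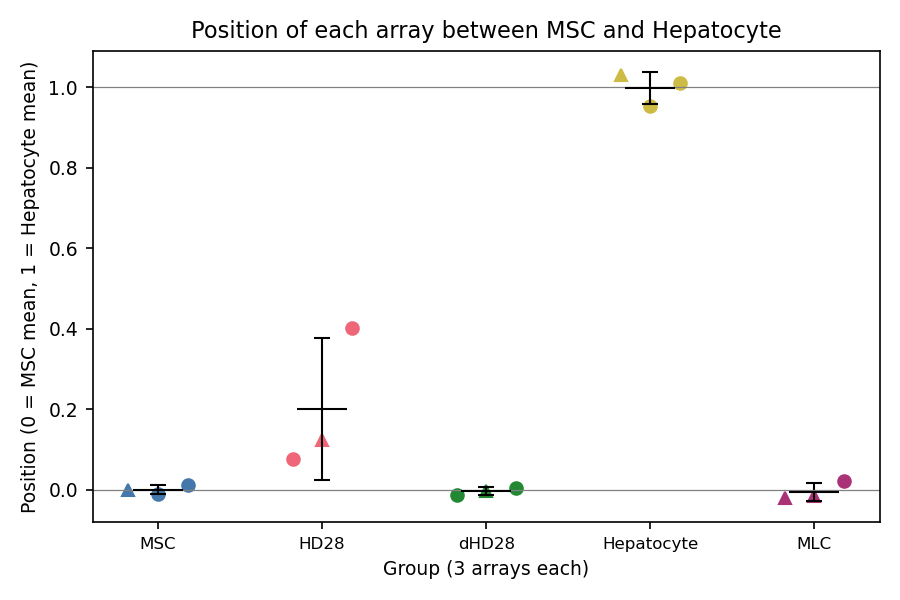
Position of each array between the MSC mean (0) and the Hepatocyte mean (1) for the 5 groups (circles, low spike-in class; triangles, high), with mean and SD (n = 3). HD28 arrays lie at 0.0763, 0.124 and 0.401, and those of dHD28 and MLC near 0.

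The comparison of HD28 with MSC asks what the hepatogenic protocol changed. Genes with the largest rises were the retinal dehydrogenase Aldh1a1, 316-fold higher (log2 8.30 ± 0.42, SE, n = 3 per group, adjusted p = 1.1e-07), its relative Aldh1a7 at 209-fold, the acute-phase protease inhibitor Serpina3n at 262-fold (log2 8.03 ± 0.31), the protease inhibitor Ctla2a at 202-fold and the lipocalin Apod at 146-fold. The largest falls were in the growth factor pleiotrophin (Ptn, log2 -5.62 ± 0.47), the smooth muscle genes Actg2 (log2 -4.99) and Cnn1 (log2 -4.85), and the matrix gene Ltbp2 (log2 -4.95). In each of these genes all 3 HD28 arrays lay on the same side of all 3 MSC arrays, as the naming rule for the largest changes requires. The MSC means of Aldh1a1 and Aldh1a7 (each 3.19) and the HD28 mean of Ptn (3.4) lie under the lower quartile of the arrays, so these sizes are approximate. In total 1231 genes changed, 590 higher and 641 lower. When arrays were centred on housekeeping genes, which moved the median of all genes by -0.26, the split was 457 higher and 1081 lower.

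Part of the listed targets of the added hormones rose in HD28. Of 20 measured glucocorticoid response genes 12 rose and 0 fell, with 14 higher adjusted over the list alone (median log2 1.95, camera adjusted p = 1e-15, adjusted p = 0.046 with an estimated correlation). Tsc22d3, which encodes the anti-inflammatory mediator GILZ, rose 15.6-fold (log2 3.97 ± 0.43), the metallothionein Mt2 rose 9.05-fold, and without HD28 replicate 3 the list had 10 higher and 1 lower. Of 23 genes of the oncostatin M and STAT3 response 6 rose, but 3 without MSC replicate 1 and 4 without MSC replicate 2 or HD28 replicate 2 (7 adjusted over the list alone, camera adjusted p = 5.1e-07, adjusted p = 0.19 with an estimated correlation). They include the lipopolysaccharide-binding protein Lbp, 27.5-fold higher (log2 4.78 ± 0.52), and the transcription factor Cebpd, 7.24-fold higher. In iron and metal handling 4 of 14 genes rose and 1 fell, or 0 without any 1 of MSC replicates 1, 2 and 3 and HD28 replicates 1 and 2 (5 and 1 adjusted over the list alone, camera adjusted p = 7.4e-05, adjusted p = 0.19 with an estimated correlation). Ceruloplasmin (Cp), a copper-carrying ferroxidase, rose 24.3-fold and the iron-regulating gene Hfe 6.33-fold.

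Proliferation genes fell. Of 29 cell cycle genes 25 were lower and 0 higher in HD28, also adjusted over the list alone (median log2 -2.03, camera adjusted p = 2.2e-19, adjusted p = 0.19 with an estimated correlation). The replication licensing genes Mcm5 (log2 -2.78 ± 0.51) and Cdc6 (log2 -2.70 ± 0.46) and the mitotic genes Cdca8 (log2 -2.85) and Birc5 (log2 -2.57) are examples. Of 24 contractile and TGF-β response genes 6 fell (7 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.71 with an estimated correlation), among them Tagln, 9.79-fold lower. The extracellular matrix genes moved both ways, with 4 of 30 higher and 4 lower, also adjusted over the list alone. The proteoglycan genes Dcn (30.7-fold) and Lum (log2 3.91) rose and the thrombospondin Thbs2 fell by 3.42 on the log2 scale (camera adjusted p = 0.008, adjusted p = 0.76 with an estimated correlation). Without MSC replicate 1 or HD28 replicate 1 the call of this list ended (adjusted p = 0.17 and 0.14), and without MSC replicate 3, HD28 replicate 1 or HD28 replicate 2 the genes that fell numbered 2. With the spike-in class as a block 6 rose, and 9 without HD28 replicate 3 as well. Of 17 osteogenic and chondrogenic genes 2 rose (3 without MSC replicate 2) and 1 fell, or 0 to 2 by the array left out (2 and 3 adjusted over the list alone, camera adjusted p = 0.54). The bone matrix gene Ibsp rose 17.4-fold (approximate, with a dim MSC mean of 3.36) and the cartilage gene Comp 5.04-fold. Of 20 imprinted genes 3 rose, also adjusted over the list alone and 2 without MSC replicate 1. They include the growth factor Igf2 at 11.1-fold and Dcn (camera adjusted p = 0.034, adjusted p = 0.56 with an estimated correlation, and 0.17 and 0.055 without MSC replicate 1 or 3).

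Hepatocyte genes rose in few cases. Of 34 secreted hepatocyte proteins only haptoglobin (Hp) changed, also adjusted over the list alone (log2 4.85 ± 0.96, adjusted p = 0.0057), and without HD28 replicate 3 it stood at 4.14 with an adjusted p of 0.024. The list median was 2.00 with all arrays (camera adjusted p = 5.8e-07, adjusted p = 0.71 with an estimated correlation) -0.23 without HD28 replicate 3 (adjusted p = 0.65) and 3.25 without HD28 replicate 1. Of 23 cytochrome P450 and conjugation enzymes 5 rose (7 adjusted over the list alone, and 3 without any 1 of the MSC arrays). The count stayed at 5 without HD28 replicate 3, where the median went from 2.37 to 0.04 (camera adjusted p = 1.3e-09 and 0.0013, adjusted p = 0.56 with an estimated correlation). The sulfotransferase Sult1a1 rose 15.8-fold (log2 3.98 ± 0.36, and 3.48 without HD28 replicate 3). Of 21 complement and coagulation genes 3 rose, also adjusted over the list alone, and 1 without HD28 replicate 3 or MSC replicate 1. Leaving out any other array gave 2 or 3. Complement factor B (Cfb) rose 10.6-fold (log2 3.41 ± 0.31, and 2.96 without HD28 replicate 3). The camera call of that list (adjusted p = 3.3e-06) ended with an estimated correlation (adjusted p = 0.71) and without HD28 replicate 3 (adjusted p = 0.26). Of 20 hepatocyte transcription factors 1 changed, Onecut2 (log2 1.12 ± 0.27), and 0 without HD28 replicate 3, where Onecut2 stood at 0.98 (adjusted p = 0.069). It also lost its call without MSC replicate 1 (1.03, adjusted p = 0.072) or HD28 replicate 1 (0.98, adjusted p = 0.071). Without HD28 replicate 2 the list had 2 that rose. By limma 0 of 19 bile acid genes, 0 of 23 urea cycle and amino acid genes and 0 of 14 gluconeogenesis genes changed, also adjusted over the list alone, and at most 2 of a list did without any 1 array. With the spike-in class as a block 2 gluconeogenesis genes rose, among them the glycogen phosphorylase Pygl (log2 3.07, adjusted p = 0.022, and 0.052 without the block), and 1 bile acid gene. With HD28 replicate 3 also left out the counts were 2, with Pygl at 1.96 (adjusted p = 0.046), and 0, and 1 urea cycle gene fell. In those lists the medians of 0.87, 1.06 and 1.12 with all arrays became 0.07, -0.09 and -0.15 without HD28 replicate 3, and the camera calls (adjusted p = 4.3e-05, 0.00041 and 0.007) ended (adjusted p = 0.73, 0.83 and 0.97) as they did with an estimated correlation (adjusted p = 0.71, 0.76 and 0.71).

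Genes that copy DNA methylation at replication fell with the cell cycle genes. The maintenance methyltransferase Dnmt1 averaged 7.65 ± 0.06 (SD, n = 3) in HD28 and 9.24 ± 0.69 in MSC, a fall of 3.01-fold (log2 -1.59 ± 0.41, adjusted p = 0.024, and 0.0062 with the spike-in class as a block). Its 3 probe sets all fell. Its partner Uhrf1, which directs Dnmt1 to newly replicated DNA, fell 5.26-fold (log2 -2.40 ± 0.47, adjusted p = 0.0055), with 1 of its 2 probe sets passing the test. The de novo methyltransferases did not pass the test, with Dnmt3a at log2 -0.20 (adjusted p = 0.74) and Dnmt3b at -0.41 (adjusted p = 0.066), nor did the demethylation genes Tet1 (0.07), Tet2 (0.85) and Tet3 (-0.62). Of 18 genes in the list 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.87). The call of Dnmt1 ended without MSC replicate 1 (log2 -1.20, adjusted p = 0.11) and, at an adjusted p of 0.062, without HD28 replicate 1, 2 or 3 (log2 -1.58, -1.63 and -1.57).

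**Figure D3:**
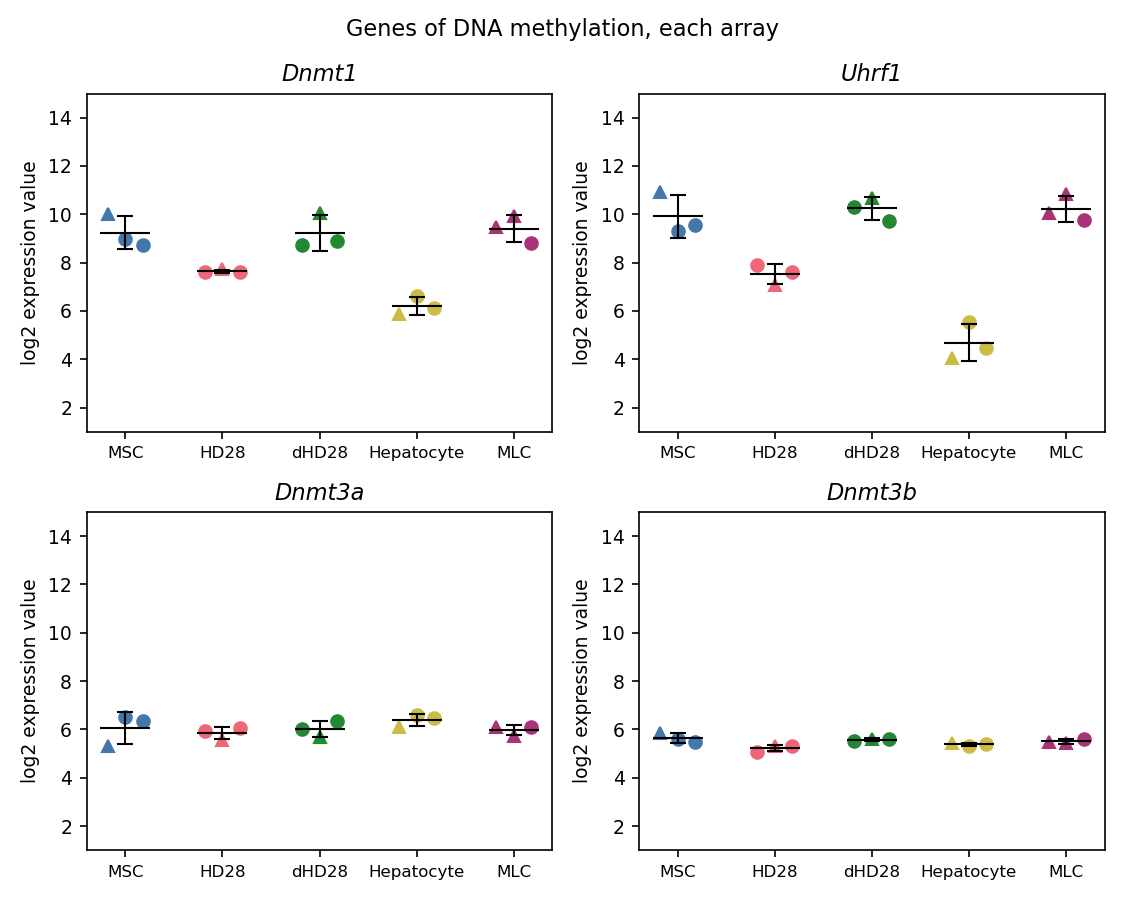
Log2 expression of Dnmt1, Uhrf1, Dnmt3a and Dnmt3b in each array of the 5 groups (circles, low spike-in class; triangles, high), with mean and SD (n = 3). Dnmt1 averages 7.65 in HD28, 6.20 in Hepatocyte and 9.24 in MSC.

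The comparison of dHD28 with HD28 asks what return to MSC medium changed. The genes with the largest changes on differentiation went the other way. Serpina3n fell 280-fold (log2 -8.13 ± 0.31, n = 3 per group), Apod 180-fold (log2 -7.49 ± 0.27), Aldh1a1 172-fold, Aldh1a7 164-fold and Ctla2a 146-fold. Ptn rose 65.4-fold (log2 6.03 ± 0.47, approximate, with a dim HD28 mean of 3.4), Actg2 50.6-fold, Cnn1 35.8-fold and the stretch-responsive gene Ankrd1 22.7-fold. The arrays of these genes did not overlap between the groups, as the naming rule for the largest changes requires. In total 1605 genes changed, 843 higher and 762 lower. After centring on housekeeping genes, which moved the median of all genes by 0.24, the split was 1311 higher and 573 lower.

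Cell cycle genes rose in dHD28, 26 of 29 with 0 lower, also adjusted over the list alone (median log2 2.27, camera adjusted p = 4e-21, adjusted p = 0.2 with an estimated correlation). Cdca8 rose 9.58-fold and Cdc6 7.89-fold. Of the glucocorticoid response genes 13 of 20 fell (14 adjusted over the list alone, camera adjusted p = 1.2e-13, adjusted p = 0.074 with an estimated correlation), with Tsc22d3 14.2-fold and Mt2 13.9-fold lower. Of the oncostatin M and STAT3 genes 9 of 23 fell (11 adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.2 with an estimated correlation), with Lbp 22.9-fold lower. In iron and metal handling 5 of 14 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.2 with an estimated correlation), with Cp 25.5-fold lower. Of the contractile and TGF-β genes 7 of 24 rose, and 1 fell in the fit with all arrays but not without HD28 replicate 1, 2 or 3, dHD28 replicate 1 or 2, MSC replicate 2 or 3, Hepatocyte replicate 2 or any MLC array (8 and 1 adjusted over the list alone, camera adjusted p = 0.00064, adjusted p = 0.65 with an estimated correlation), with Tagln 12.7-fold higher. In the matrix list 3 of 30 rose and 6 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.77 with an estimated correlation, and 0.071 without HD28 replicate 1, where 4 fell, as without dHD28 replicate 1). The genes that rose numbered 2 without HD28 replicate 2 or dHD28 replicate 1 or 3. There Dcn fell 56.5-fold, Lum 17.6-fold, and Thbs2 rose 10.2-fold. Among imprinted genes 4 of 20 fell, or 2 without dHD28 replicate 1 and 6 without Hepatocyte replicate 1 (5 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.54 with an estimated correlation), with Igf2 13.9-fold lower.

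Of 7 hepatocyte lists 6 fell by camera with all arrays, but with an estimated correlation none did (adjusted p = 0.65 for 2 and 0.77 for 4). Most of the fall rested on HD28 replicate 3. The list of transcription factors did not pass (median log2 -0.26, camera adjusted p = 0.14, adjusted p = 0.77 with an estimated correlation), with 2 of 20 lower, also adjusted over the list alone. Without HD28 replicate 1 or 2 it did (0.022 and 0.021), and 0 genes were lower without HD28 replicate 3 or dHD28 replicate 1 and 1 without HD28 replicate 1 or dHD28 replicate 3. Of 34 secreted proteins 1 fell, also adjusted over the list alone, Hp (log2 -5.41 ± 0.96), and the list median of -2.10 became 0.12 without HD28 replicate 3 (camera adjusted p = 4.1e-06 and 0.9). The urea cycle list went from -1.19 to 0.06 (camera adjusted p = 0.00089 and 0.97) and the gluconeogenesis list from -1.08 to 0.06 (camera adjusted p = 0.02 and 0.92, and 0.073 without dHD28 replicate 3), each with 0 genes changed by limma with all arrays, also adjusted over the list alone. With the spike-in class or the replicate number as a block 2 gluconeogenesis genes fell, and 1 with the class block and without HD28 replicate 3, where 1 urea cycle gene rose. The bile acid list had 2 of 19 genes lower with all arrays (3 adjusted over the list alone), 0 without HD28 replicate 3, dHD28 replicate 1 or dHD28 replicate 2, and 1 to 3 without others (camera adjusted p = 4e-05 and 0.21), with 3 lower under either block. With an estimated correlation these 4 lists had an adjusted p = 0.77. Among cytochrome P450 and conjugation enzymes 6 of 23 fell (7 adjusted over the list alone), 5 without HD28 replicate 3, 3 without dHD28 replicate 1 or 2 and 4 without dHD28 replicate 3 (camera adjusted p = 3.2e-08 and 0.0022, adjusted p = 0.65 with an estimated correlation), with Sult1a1 17.9-fold lower (log2 -4.16, and -3.66 without HD28 replicate 3). Of 21 complement and coagulation genes 4 fell, also adjusted over the list alone, 3 without HD28 replicate 3 and 2 without dHD28 replicate 2 (camera adjusted p = 2.1e-06 and 0.031, adjusted p = 0.65 with an estimated correlation), with Cfb 10.8-fold and coagulation factor F7 4.08-fold lower (log2 -3.43 and -2.03, and -2.98 and -1.59 without HD28 replicate 3).

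Dnmt1 rose 2.97-fold in dHD28 against HD28 (log2 1.57 ± 0.41, adjusted p = 0.021, and 0.0054 with the spike-in class as a block) and Uhrf1 6.56-fold (log2 2.71 ± 0.47, adjusted p = 0.002). Dnmt3a (log2 0.16, adjusted p = 0.8) and Dnmt3b (log2 0.35, adjusted p = 0.1) did not pass the test. In the list of 18 DNA methylation genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.88), and 1 rose and 0 fell without any 1 of HD28 replicates 1, 2 and 3 or dHD28 replicate 2. Leaving out others gave 2 or 3 that rose, and with the replicate number as a block 0 fell. Among histone modifiers the Polycomb methyltransferase Ezh2 rose (log2 1.16 ± 0.27) and its paralogue Ezh1 fell (log2 -1.40 ± 0.27, in 1 of 4 probe sets). In all 1 of 23 was higher and 1 lower, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.42). Leaving out HD28 replicate 1 or 3 or dHD28 replicate 2 or 3 gave 2 higher. The call of Dnmt1 ended without HD28 replicate 1, 2 or 3 (log2 1.56, 1.61 and 1.55, adjusted p = 0.055, 0.056 and 0.055) and without dHD28 replicate 2 (log2 1.15, adjusted p = 0.091). That of Ezh2 ended without dHD28 replicate 1 (log2 0.97, adjusted p = 0.063).

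The comparison of dHD28 with MSC asks what remained of the differentiation. Dnmt1 differed by log2 -0.02 ± 0.41, Uhrf1 by 0.32 ± 0.47, Dnmt3a by -0.04 ± 0.29 and Dnmt3b by -0.06 ± 0.13 (n = 3 per group, each with an adjusted p of 1). Saa3, an acute-phase gene with the largest difference in the oncostatin M list, stood at 5.38 ± 0.42 in dHD28 and 7.17 ± 2.64 in MSC, and the proteoglycan Dcn at 6.71 ± 1.01 and 7.59 ± 1.67. By limma 0 genes changed, in no list did a member change, and the largest absolute log2 difference was 1.79. At an unadjusted p under 0.05 there were 205 genes, where 910 would be expected by chance, and between 1 (treat) and 1643 (array weights) under the alternatives. Leaving out MSC replicate 1, dHD28 replicate 2 or dHD28 replicate 3 gave 762, 481 and 556, and leaving out MSC replicate 3 or dHD28 replicate 1 gave 122 and 67. The treat test also called 0. Cell cycle genes had a median difference of 0.16 and a camera adjusted p of 0.00083, lost with an estimated correlation (adjusted p = 0.99), without MSC replicate 3 (0.5) or without dHD28 replicate 2 (0.099). Some lists had a call only when an array was left out. The matrix list had a median of -0.51 without MSC replicate 1 (camera adjusted p = 8.6e-05) and -0.19 without dHD28 replicate 1 (0.036). The interferon list had 0.34 without MSC replicate 3 (0.0036), 0.24 without dHD28 replicate 1 (0.017) and 0.56 without dHD28 replicate 2 (2.4e-05), and the contractile list 0.26 without dHD28 replicate 2 (0.037). For 84% of genes the 95% confidence interval lay within 1 log2 unit on either side of 0, and in the rest larger differences are not excluded.

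Primary hepatocytes against MSC give the scale of the target state. The fibrinogen gene Fga stood at 13.11 in hepatocytes and 2.44 in MSC (log2 10.68 ± 1.70, n = 3 per group), the drug-metabolising Cyp3a11 at 13.64 and 3.00, the fatty acid carrier Fabp1 at 13.59 and 3.00, and Alb at 14.12 and 3.90 (log2 10.22 ± 1.90). The MSC means of the first 3 lie under the lower quartile of the arrays and Alb in hepatocytes holds the highest value of the table (14.15), so no exact fold is given. Their standard errors include the spread of HD28 replicate 3, since the SD of Alb was 0.02 in hepatocytes and 0.06 in MSC. The 3' to 5' difference of actin probes was 1.05 ± 0.33 (SD, n = 3) in hepatocytes and 0.309 ± 0.16 in MSC, and what this adds to the comparison was not tested. Lower in hepatocytes were the Wnt modulator Sfrp2, 742-fold (log2 -9.53 ± 0.29), Col1a1, 460-fold (log2 -8.84 ± 0.29), S100a4, 404-fold, the mesenchymal cadherin Cdh11, 352-fold, and the collagen cross-linking enzyme Lox, 297-fold. The arrays of these genes did not overlap between the groups, as the naming rule for the largest changes requires. The Hepatocyte means of Sfrp2 (2.93) and Cdh11 (2.88) lie under the lower quartile of the arrays, so their folds are approximate. In total 5476 genes changed, 2149 higher and 3327 lower. After centring on housekeeping genes, which moved the median of all genes by 0.41, the split was 3313 higher and 2329 lower. In the deposited scaling these housekeeping genes averaged 10.32 in Hepatocyte, 10.91 in MSC, 10.82 in HD28 and 10.97 in MLC. The centring takes them as equal. Whether they or the other genes moved was not tested, here and in later comparisons with Hepatocyte.

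All 23 urea cycle and amino acid genes, all 23 cytochrome P450 and conjugation enzymes and all 19 bile acid genes were higher in hepatocytes, as were 33 of 34 secreted proteins, 16 of 20 hepatocyte transcription factors, 13 of 14 gluconeogenesis genes and 20 of 21 complement and coagulation genes. Adjusted over the list alone these counts were equal. Examples are the urea cycle enzyme Otc (932-fold), the bile acid importer Slc10a1 (281-fold), the nuclear receptor Hnf4a (52.0-fold, log2 5.70 ± 0.69) and glucose-6-phosphatase G6pc (267-fold). The MSC means of Otc (2.17) and G6pc (3.50) lie under the lower quartile of the arrays, so their folds are approximate. Of 27 epithelial junction and keratin genes 17 were higher (18 higher and 1 lower adjusted over the list alone), with Krt18 258-fold (approximate, with a dim MSC mean of 3.13) and Krt8 76.4-fold. Camera adjusted p ran from 4.6e-14 (secreted proteins) to 6.8e-07 (gluconeogenesis), and adjusted p = 0.17 to 0.24 with an estimated correlation. Markers of other liver cells were higher as well, 16 of 20 for macrophages and Kupffer cells and 15 of 18 for endothelium, with 0 lower, also adjusted over the list alone (camera adjusted p = 8.9e-08 and 2.3e-07, adjusted p = 0.24 with an estimated correlation). The Kupffer cell receptor Vsig4 was 32.9-fold higher and the sinusoidal endothelial lectin Clec4g 31.1-fold. Of 13 stellate cell markers 7 were higher and 1 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.49 with an estimated correlation), with Rgs5 49.3-fold higher (approximate, with a dim MSC mean of 3.45). The call of that list ended without MSC replicate 3 (adjusted p = 0.052) or Hepatocyte replicate 2 (0.065) or 3 (0.1, with 2 lower), and after centring on housekeeping genes (0.072).

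Lower in hepatocytes were 25 of 30 matrix genes, with 2 higher, or 1 without MSC replicate 1, HD28 replicate 2, Hepatocyte replicate 2 or 3 or MLC replicate 1 (camera adjusted p = 2e-12), 13 of 16 regulators of epithelial to mesenchymal transition (2e-06), 18 of 24 contractile and TGF-β genes, with 1 higher (2.4e-06), and all 29 cell cycle genes (3.3e-17). Adjusted over the list alone 26 matrix genes were lower and the other counts were equal. With an estimated correlation these 4 lists had an adjusted p = 0.17, 0.087, 0.21 and 0.17. Col1a2 fell by 6.75 on the log2 scale, the mesenchymal transcription factor Prrx1 by 6.69, smooth muscle actin Acta2 by 6.25 and Top2a, an enzyme of dividing cells, by 6.22. With the probe sets most open to cross-hybridisation left out, Acta2 was read from another probe set and differed by -0.53 (adjusted p = 0.4). Of 21 stromal surface markers 9 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.14), with the growth factor receptor Pdgfrb 83.8-fold and Cd44 20.7-fold lower. Of 15 posterior Hox genes 5 were lower and 0 higher (camera adjusted p = 0.0073, adjusted p = 0.21 with an estimated correlation), including Hoxc10, 76.6-fold, and Hoxa9, 51.9-fold. Both folds are approximate, with dim Hepatocyte means of 3.48 and 3.45. Of 16 ribosomal protein genes 10 were lower (camera adjusted p = 1.3e-07, adjusted p = 0.17 with an estimated correlation). There Rps19 fell by 1.34 and Rpl8 by 1.37, and by 0.93 and 0.97 after centring on housekeeping genes, under the fold limit. Adjusted over the list alone the Hox and ribosomal counts were equal.

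Dnmt1 was 8.21-fold lower in hepatocytes than in MSC (6.20 ± 0.38 against 9.24 ± 0.69, log2 -3.04 ± 0.41, adjusted p = 3.6e-05) and Uhrf1 37.7-fold lower (log2 -5.24 ± 0.47). Dnmt3a (log2 0.34, adjusted p = 0.37) and Dnmt3b (log2 -0.26, adjusted p = 0.12) did not pass the test. In the list 6 of 18 genes were lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.41), with 1 higher without MSC replicate 1 or any Hepatocyte array. The glycosylase Mbd4 fell by 1.41 on the log2 scale and Gadd45b by 1.69, and the methyl-binding gene Mbd1 rose by 1.29, or by 0.87 without Hepatocyte replicate 3, which ends its call by the fold limit. Of 23 histone modifiers 10 were lower, also adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.17 with an estimated correlation), with Ezh2 7.43-fold and the deacetylase Hdac1 3.26-fold lower. Of 20 imprinted genes 2 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.72), with 5 lower without MSC replicate 1 and 1 to 3 higher without others, with Ndn at log2 -5.11 and Grb10 at -4.58.

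HD28 against hepatocytes measures the distance left after differentiation. The collagenase Mmp13 was 812-fold higher in HD28 (log2 9.67 ± 1.68), Col1a1 537-fold, Lox 526-fold and Cdh11 512-fold. The folds of Mmp13 and Cdh11 are approximate, since their Hepatocyte means (2.69 and 2.88) lie under the lower quartile of the arrays. Cyp3a25 (log2 -7.89 ± 1.42), the protease inhibitor Mug1 (-7.85), Fga (-7.77) and Otc (-7.70) were lower, with Otc at 4.34 ± 3.76 (SD, n = 3) in HD28 because of replicate 3. Without that array they stood at -10.44, -10.57, -10.81 and -9.87, which are approximate, since HD28 then lies under the lower quartile of the arrays. The 3' to 5' difference of actin probes was 0.488 ± 0.40 in HD28 and 1.05 ± 0.33 in hepatocytes, and its part was not tested. In total 4825 genes changed, 2786 higher and 2039 lower. After centring on housekeeping genes, which moved the median of all genes by -0.67, 7665 changed, 1591 higher and 6074 lower.

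Of the hepatocyte lists, 32 of 34 secreted proteins (33 adjusted over the list alone), 16 of 20 transcription factors and all 19 bile acid genes remained lower in HD28 than in hepatocytes (camera adjusted p = 3.8e-10, 1.5e-08 and 1.4e-10, adjusted p = 0.31, 0.19 and 0.27 with an estimated correlation). Without HD28 replicate 3 the counts were 34, 16 and 19. Foxa3 was 28.1-fold and Hnf4a 26.2-fold lower (log2 -4.81 and -4.71, and -5.50 and -5.89 without HD28 replicate 3). Matrix genes were higher, 26 of 30 (27 adjusted over the list alone, camera adjusted p = 1.4e-16, adjusted p = 0.18 with an estimated correlation), as were 12 of 16 regulators of epithelial to mesenchymal transition, also adjusted over the list alone (camera adjusted p = 2.5e-07, adjusted p = 0.049 with an estimated correlation). Cell cycle genes were also higher, 27 of 29, also adjusted over the list alone (median log2 2.45, camera adjusted p = 1.1e-11, adjusted p = 0.22 with an estimated correlation), with Top2a 20.3-fold higher. Timp1, a metalloproteinase inhibitor, was 117-fold and the oncostatin M receptor Osmr 39.3-fold higher. In that list 7 of 23 genes were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.3). Uhrf1 was 7.16-fold higher (log2 2.84 ± 0.47, with 1 of 2 probe sets passing the test) and Dnmt1 2.73-fold (log2 1.45 ± 0.41, adjusted p = 0.011). After centring on housekeeping genes Dnmt1 differed by 0.78 (adjusted p = 0.14) and did not pass the test. Dnmt3a then stood at -1.21 (adjusted p = 0.00094), against -0.54 (adjusted p = 0.15) in the deposited scaling. That centring takes the housekeeping genes as equal, but they averaged 10.32 in Hepatocyte and 10.82 in HD28 in the deposited scaling.

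MLC against hepatocytes compares the cells labelled as hepatocytes kept in MSC medium with the hepatocytes. The comparison cannot show that MLC arose from hepatocytes, so rises and falls here are differences between the groups. Sfrp2 rose 595-fold (log2 9.22 ± 0.29, n = 3 per group), S100a4 434-fold, Col1a1 425-fold (log2 8.73 ± 0.29), Cdh11 362-fold and Lox 331-fold. The folds of Sfrp2 and Cdh11 are approximate, since their Hepatocyte means (2.93 and 2.88) lie under the lower quartile of the arrays. Cyp3a11 fell from 13.64 to 2.86 (log2 -10.78 ± 1.92), Fga from 13.11 to 2.38, Cyp3a25 from 12.80 to 2.33 and Alb from 14.12 ± 0.02 to 3.85 ± 0.18 (SD). In MLC the first 3 lie under the lower quartile of the arrays, and Alb in hepatocytes is at the top of the table, so no exact fold is given. The 3' to 5' difference of actin probes was 1.05 ± 0.33 (SD, n = 3) in hepatocytes and 0.223 ± 0.15 in MLC, and what this adds to the comparison was not tested. The arrays of these genes did not overlap between the groups, as the naming rule for the largest changes requires. In total 5541 genes changed, 3353 higher and 2188 lower. After centring on housekeeping genes, which moved the median of all genes by -0.48, the split was 2208 higher and 3930 lower.

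All 34 secreted proteins, all 23 cytochrome P450 and conjugation enzymes, all 19 bile acid genes, all 23 urea cycle genes and 16 of 20 hepatocyte transcription factors fell in MLC, also adjusted over the list alone (camera adjusted p from 3.5e-12 for bile acid genes to 7.1e-09 for transcription factors, adjusted p = 0.17 to 0.25 with an estimated correlation). Krt18 fell 279-fold (approximate, with a dim MLC mean of 3.02) and Hnf4a 57.0-fold. All 29 cell cycle genes rose (camera adjusted p = 4.3e-18), as did 25 of 30 matrix genes, with 2 lower, or 1 without Hepatocyte replicate 2 or 3 or MLC replicate 1 or 2 (5.3e-12), 13 of 16 regulators of epithelial to mesenchymal transition (7.6e-07) and 19 of 24 contractile and TGF-β genes, with 2 lower (1.3e-06). Adjusted over the list alone these counts were equal, and with an estimated correlation the adjusted p was 0.17, 0.19, 0.067 and 0.24. Acta2, a target of TGF-β, rose 75.8-fold (log2 6.24 ± 0.59, but 0.38 with an adjusted p of 0.54 in another probe set), Pdgfrb 73.1-fold and Top2a 97.8-fold. Markers of Kupffer cells fell in 17 of 20 cases and those of endothelium in 15 of 18, also adjusted over the list alone (camera adjusted p = 1.1e-07 and 1.7e-07, adjusted p = 0.24 with an estimated correlation), with Vsig4 38.5-fold and Clec4g 38.1-fold lower. Of 15 posterior Hox genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.24 with an estimated correlation), with Hoxc10 71.7-fold and Hoxa9 51.4-fold higher. Both folds are approximate, with dim Hepatocyte means of 3.48 and 3.45.

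Dnmt1 rose 9.21-fold in MLC, to 9.41 ± 0.58 (log2 3.20 ± 0.41, adjusted p = 2.2e-05, and log2 3.01 with the spike-in class as a block), Uhrf1 46.1-fold (log2 5.53 ± 0.47) and Ezh2 10.8-fold (log2 3.44 ± 0.27). Dnmt3a (log2 -0.43, adjusted p = 0.25) and Dnmt3b (log2 0.12, adjusted p = 0.48) did not pass the test. Of 18 genes in the DNA methylation list 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.41), with 1 lower without HD28 replicate 2 or 3, any Hepatocyte array or MLC replicate 1 or 2. With the spike-in class as a block 6 rose and 1 fell, since Gadd45g (log2 1.42, adjusted p = 0.047 and 0.055 with the block) and Zbtb33 (-1.08 and -0.86) did not pass. Among the list Gadd45b rose by 2.10, and Mbd4 by 1.42, or by 0.94 after centring on housekeeping genes. Mbd1 fell by 1.41, or by 0.99 without Hepatocyte replicate 3, which ends its call by the fold limit.

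Against MSC, MLC showed 0 changed genes by limma and by treat, and in no list did a member change. Dnmt1 differed by log2 0.17 ± 0.41, Uhrf1 by 0.29 ± 0.47, Dnmt3a by -0.09 ± 0.29 and Dnmt3b by -0.14 ± 0.13 (n = 3 per group, each with an adjusted p of 1). Among posterior Hox genes, which mark position along the body axis, Hoxa11 differed by -0.23 ± 0.16, and among cytokines Il6 by 0.98 ± 0.67. The largest absolute log2 difference was 1.40. At an unadjusted p under 0.05 there were 91 genes, where 910 would be expected by chance, and between 0 (treat) and 1549 (array weights) under the alternatives. Leaving out MSC replicate 1 or MLC replicate 3 gave 292 and 305, and leaving out MLC replicate 1 or 2 gave 42 and 45. Cell cycle genes had a median difference of 0.26 and a camera adjusted p of 3.4e-07, lost with an estimated correlation (adjusted p = 0.99) and without MSC replicate 3 (0.24). The matrix list had a median of -0.37 and a call without MSC replicate 1 (camera adjusted p = 3.1e-05), the imprinted list -0.29 without the same array (0.013), and the oncostatin M list 0.15 and 0.17 without MLC replicate 1 or 2 (0.028 and 0.024). For 85.8% of genes the 95% confidence interval lay within 1 log2 unit on either side of 0. Arrays of different groups among MSC, dHD28 and MLC correlated across genes with a median r of 0.985 over 27 pairs and arrays of the same group with 0.979 over 9 pairs. Within a spike-in class the medians were 0.993 and 0.987. Some pairs across groups exceeded the best same-group pair (0.9935), such as MSC replicate 3 with MLC replicate 3 (0.9965) and MSC replicate 1 with dHD28 replicate 2 (0.9957). MSC replicate 1 had only 0.9651 and 0.9648 with the other MSC arrays. This spread within groups enters the errors behind the 0 changed genes. Genes are not independent replicates, so no p is given.

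**Figure D4:**
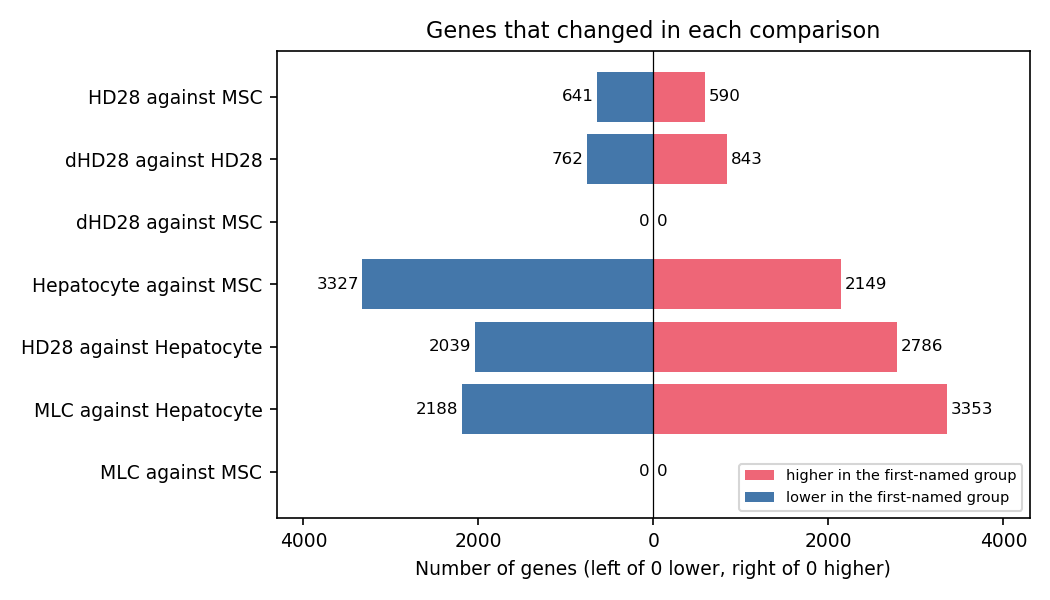
Number of genes higher (right) and lower (left) in the first-named group of each of 7 comparisons, by limma with an adjusted p under 0.05 and a fold of at least 2. The bars for dHD28 and MLC against MSC are at 0, and that of MLC against Hepatocyte reaches 3353 higher.

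Reversal was counted gene by gene. Of the 590 genes that rose in HD28, such as Serpina3n, Apod and Aldh1a1, 554 fell in dHD28 (93.9%), where independent sets would share 24.7. Of the 641 that fell, such as Ptn, Actg2 and Cnn1, 597 rose again (93.1%, independent 29.7). The shares that reversed were 75.2% and 76.8% without dHD28 replicate 2 and 84.8% and 86% without dHD28 replicate 1. For genes that rose the share was 96% without MSC replicate 1 and 90.7% without MSC replicate 3. For genes that fell it was 87.8% without MSC replicate 1, 90.7% without MSC replicate 2 and 90.5% without dHD28 replicate 3. By limma 0 of either set differed between dHD28 and MSC. The sets share the HD28 arrays. In simulations without any group difference the covariance of the log2 changes across genes was -0.048, against -0.538 measured. The simulated overlap was 0, but almost no genes pass where no group differs, so it does not test sets of this size. With 3 HD28 arrays the group cannot be split into parts of at least 2, so part of the excess may come from the shared arrays.

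The part of the hepatocyte profile seen in HD28 was smaller. Of the 590 genes that rose in HD28, 229 were also higher in hepatocytes than in MSC (38.8%, independent 69.7, simulated mean 0.01), and 116 were lower (independent 108). Without HD28 replicate 3 the overlap was 158 and without MSC replicate 1 it was 130. Of the 641 that fell, which include 25 cell cycle genes, 546 were also lower in hepatocytes (85.2%, independent 117). The log2 changes of these comparisons correlated across genes with r = 0.475, where simulations of unchanged groups that share the MSC arrays gave 0.5. The covariance was 0.588 and the simulated one 0.048, and part of the overlap may come from the shared arrays. The simulated mean overlap of 0.01 is no test of it, since almost no genes pass where no group differs. Of 2149 genes higher in hepatocytes 2056 fell in MLC (95.7%, independent 258) and of 3327 lower 3157 rose (94.9%, independent 613). The hepatocyte arrays are shared there, with a measured covariance of -2.97 and a simulated one of -0.048.

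The changes on return differed in 4314 genes between the hepatocyte and the HD28 origin, 2502 with a higher and 1812 with a lower change in MLC. After centring on housekeeping genes 7787 differed, 1398 higher and 6389 lower. Cell cycle genes had a larger rise in MLC, with a positive difference in 26 of 29, also adjusted over the list alone (median log2 2.50, camera adjusted p = 1e-11, adjusted p = 0.22 with an estimated correlation). The list means were alike in MLC (9.96) and dHD28 (9.91) but not in Hepatocyte (5.41) and HD28 (7.79). The contrast thus compares how far the origins lay from a like end level. For Birc5 the rises were 6.83, approximate since its Hepatocyte mean is dim (3.66), and 2.79 on the log2 scale. Matrix genes differed in 25 of 30 cases, also adjusted over the list alone (median log2 5.66, camera adjusted p = 1.5e-18, adjusted p = 0.18 with an estimated correlation). Dnmt1 rose by 3.20 in MLC and 1.57 in dHD28, a difference of 1.63 ± 0.57 (adjusted p = 0.048, and 0.067 without HD28 replicate 3), and Uhrf1 by 5.53 and 2.71, a difference of 2.81 ± 0.66 (adjusted p = 0.0058). Genes that fell in both returns numbered 275 (independent 91.6) and genes that rose in both 679 (independent 155).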

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

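The tests of the sample's mixture, of further differentiation, of an array label and of the spike-in class for HD28 replicate 3, and those of the spike-in class and of positional genes for the likeness of MSC, dHD28 and MLC, and the splits that part the replicate numbers, were chosen only after the result was seen.

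The changes on return were compared directly, and 4314 genes differed between the hepatocyte and the HD28 origin. Birc5 rose by 6.83 in MLC and 2.79 in dHD28, a difference of 4.05 ± 0.65 (SE, n = 3 per group, adjusted p = 0.00047). The size for Birc5 is approximate, since its Hepatocyte mean (3.66) lies just under the lower quartile of its arrays. Uhrf1 differed by 2.81 ± 0.66 (adjusted p = 0.0058), Ezh2 by 2.28 ± 0.38 (adjusted p = 0.00063) and Dnmt1 by 1.63 ± 0.57 (adjusted p = 0.048, but 0.067 without HD28 replicate 3). Dnmt1 and Uhrf1 rose in both returns. Of the 4314 genes, 106 fell and 217 rose in both returns, 1452 fell and 1647 rose in MLC alone, 216 and 53 did so in dHD28 alone, 145 fell in dHD28 and rose in MLC, 17 did the reverse and 461 passed the test in neither. As MLC and dHD28 both lay near MSC, the difference compares how far Hepatocyte and HD28 lay from it. Of 100 drawn splits of the arrays 1, the real one, gave a count as large, and the highest other was 4049. Those draws ignore the replicate numbers, which may pair HD28 with dHD28 and dHD28 with MLC, though the labels do not say so. Of 100 splits that part the numbers as the real one does, 3 gave a count as large, with a highest other of 5038. The 2 that are not real keep the hepatocyte arrays together and mix the HD28, dHD28 and MLC arrays. MSC arrays were not moved. As such mixing gave more genes than the real groups, the count cannot tell whether the returns differ beyond the hepatocyte arrays standing apart.

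Hepatocyte transcripts stood high in HD28 replicate 3 alone among the HD28 arrays, with Alb at 13.8, Apoa1 at 12.77 against 5.12 and 5.29, and Hnf4a at 8.58 against 4.92 and 5.13, and its 3' to 5' difference of actin was 0.94 against 0.29 and 0.23. The tables argue against a hepatocyte array with an HD28 label, since over the 2827 genes called higher in the other HD28 arrays than in Hepatocyte the array had lost a median share of 0.0777 of the difference (quartiles -0.0142 to 0.184), and against the spike-in class, since HD28 replicates 1 and 3 are both of the low class and differ by a median of 4.25 over 147 hepatocyte list genes. Further differentiation of the stromal cells would leave macrophage and endothelial markers low, but the 11 of 38 at least 3 log2 units higher in Hepatocyte than in the other HD28 arrays all stood above those arrays, at a median share of 0.153 of the hepatocyte level (quartiles 0.123 to 0.163). Hepatocyte genes with that difference and a Hepatocyte mean under 12 stood at a median share of 0.133 (84 genes, quartiles 0.0992 to 0.165, up to 2.04 for Cyp4a14), a ratio of 1.15 between the sets, or 1.02 with brighter genes such as Alb (133 genes, share 0.149). RNA or cells of the primary hepatocyte preparation, in which those markers are present too, may therefore have entered this sample, and where this happened stays open.

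MSC, dHD28 and MLC arrays were at least as alike between groups as within them, although MLC came from hepatocytes by the labels. Some pairs across groups, such as MSC replicate 3 with MLC replicate 3 (r = 0.9965), exceeded the best same-group pair (0.9935). With the spike-in class as a block limma called 0 genes between MLC and MSC (308 at an unadjusted p under 0.05). This cannot decide whether the class hides differences, since MLC replicate 1, of the high class, may not follow it in expression. Its r was 0.9744 with MSC replicate 1, 0.9763 with dHD28 replicate 2 and 0.987 with MLC replicate 2, all high. With the low arrays of MSC, dHD28 and MLC it ran from 0.9853 to 0.9909. Too few arrays are argued against by the 90% of simulated genes changed by 2 log2 units that were called, though at 1 log2 unit 39% were. The 5 posterior Hox genes that differ between Hepatocyte and MSC regained a median share of 0.998 of that difference in MLC (0.985 to 1.05). These genes thus stood at the MSC level. With 0 genes changed between MLC and MSC such a share is likely for any genes so chosen. It is therefore no separate test of positional genes kept from the liver. Whether MLC samples hold cells of the source of the MSC arrays cannot be told apart from conversion of hepatocytes, because 0 of 4 sex-linked genes (Xist, Eif2s3y, Kdm5d and Uty) differed by over 2 log2 units between Hepatocyte and MSC (largest 1.11). Conversion in culture with TGF-β1 and outgrowth of stromal cells of the liver preparation likewise stay open and were not tested.

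The 6 arrays of a pair of groups make 10 splits, too few for a share under 0.05. The real split and the highest other gave 1231 and 0 genes for HD28 against MSC, 1605 and 0 for dHD28 against HD28, 5476 and 0 for Hepatocyte against MSC, 4825 and 4 for HD28 against Hepatocyte, and 5541 and 0 for MLC against Hepatocyte. In each of these, 1 of 10 splits gave as many. For dHD28 against HD28, where the numbers may pair the samples, 4 splits part all 3 pairs, and the 3 that are not real mix the groups in both parts and gave 0. For dHD28 against MSC all 10 splits gave at least the real 0, and the split that put both arrays of high spike-in signal together with dHD28 replicate 1 gave 407, which points to a structure of the samples. For MLC against MSC all 10 did, and the split that followed the spike-in class gave 5. With the class as a block both comparisons had 0 genes by limma, with 330 and 308 at an unadjusted p under 0.05.

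For results that use all groups 100 splits were drawn. A count as large as the real one came in 1 of 100 for the 8508 genes that differ among groups (highest other 7286), for the 554 genes that rose in HD28 and fell in dHD28 (541) and for the 597 that fell and rose (556). In 100 splits that part the replicate numbers as the real one does, 2 gave as many in each case. The highest other was 8510, 570 and 604, and the median other was 0. The other of the 2 kept HD28 and Hepatocyte arrays each together among the 5 groups, and exchanged replicate 3 of MSC and dHD28, which are alike, for the reversals. These counts therefore show that HD28 arrays, and for the F test Hepatocyte arrays too, stand apart. They do not tell the remaining groups from each other. The 229 genes higher in both HD28 and Hepatocyte were reached in 3 of 100, with a highest other of 2440. Some splits share several times as many genes. The draws can give hepatocyte arrays the MSC label, which makes them the reference of both comparisons. Both changes then run from hepatocytes to other cells and can share many genes. These splits therefore do not test whether HD28 and Hepatocyte share genes beyond chance. Which arrays drive those splits was not tested.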

How the results depend on the processing

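The spike-in class block, that block without HD28 replicate 3, and the fits of low spike-in arrays were chosen only after the result was seen. Under the alternatives other than leaving 1 array out alone, 227 summary values stayed within their spread or within 1.5 times and 33 moved, and with 1 array left out 244 stayed and 11 moved. For named genes 3755 calls were as before, 96 ended and 6 appeared, and with 1 array left out 4000, 136 and 4. For lists the counts were 3025, 156, 69 and 5 reversed, and 3170, 33, 48 and 4.

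With every probe set on its own the counts were 1930, 2626, 9121, 8041 and 9317 for HD28 against MSC, dHD28 against HD28, Hepatocyte against MSC, HD28 against Hepatocyte and MLC against Hepatocyte, since more probe sets were tested. The F test then gave 13945, the difference between returns 6692, the reversal of genes that rose 91.1% and the overlap of HD28 and Hepatocyte 359. With no fold limit 1948, 2562, 8149 (HD28 against Hepatocyte) and 8488 (MLC against Hepatocyte) genes passed, and the reversal of genes that fell was 89.1%. The treat test against 1.5 gave 429, 587 and 2782 (difference between returns), a reversal of 96.6% and an overlap of 87. Centring on the median gave reversals of 91.6% and 95.1%, and centring on housekeeping genes 88.4% for genes that fell, 7665 genes for HD28 against Hepatocyte and 7787 for the returns. With only the arrays compared the overlap was 134, and array weights gave reversals of 90.6% and 84.9%. The class block without HD28 replicate 3 gave 90.9% for genes that fell. Only low spike-in arrays gave 789 for HD28 against MSC, reversals of 95.9% and 85.7%, an overlap of 141 and an MLC position of 0.0228, with fewer arrays and 1 for MLC. Where no construction is named the cause was not tested.

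Without HD28 replicate 3 the median of secreted proteins turned to -0.23 and that of urea cycle genes to -0.09 in HD28 against MSC (3.25 and 1.75 without HD28 replicate 1), and to 0.12 and 0.06 in dHD28 against HD28 (-3.26 and -1.74 without HD28 replicate 1). With the class block as well they were -0.23, -0.1, 0.14 and 0.09. This array carries the hepatocyte transcripts. In low spike-in arrays cholesterol synthesis stood at 0.16 in MLC against MSC (adjusted p = 0.027), which rests on 1 MLC array against 2 of MSC and says little of the group. With 1 array left out the reversal of genes that rose ran from 75.2% to 96% and of those that fell from 76.8% to 94.1%, the overlap from 130 to 242 and the dHD28 position from -0.00863 to 0.0124. The counts ran from 853 to 1256, 1162 to 1920, 5335 to 5530, 4514 to 4948 and 5344 to 5614.

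The labels do not pair samples by number. Over all groups 14 of 30 pairs of the same number had a correlation of deviations over 0.1 (-0.68 to 0.78), and not every sample correlated best with its own number. MSC replicate 3 had 0.69 with dHD28 replicate 3 and 0.77 with MLC replicate 3, all of the low spike-in class. MSC replicate 2, of the low class, had -0.64 and -0.68 with replicate 2 of dHD28 and MLC, both of the high class. With the replicate block the counts were 1301, 1691, 5503, 4858 and 5574, with 0 by limma for dHD28 and MLC against MSC. In dHD28 against HD28 the block ended the call of Apobec1 (log2 -1.19, adjusted p = 0.058) and gave a camera call to the macrophage list (adjusted p = 0.037). It changed no other call of a named gene or list there, nor of the genes named for the difference between returns, where 4425 genes passed. Signal near background limits dim genes, and leaving those out moved no count of changed genes by over 1.5 times. At an unadjusted p under 0.05 it gave 86 genes for dHD28 and 28 for MLC against MSC, from 205 and 91. The number of arrays limits small changes, since simulated genes changed by 1 log2 unit were called in 31% of cases for dHD28 against MSC and 39% for MLC against MSC.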

Other observations

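No test in this part was chosen only after the result was seen. All 17 fatty acid oxidation genes were higher in Hepatocyte than in MSC, also adjusted over the list alone (median log2 2.73, camera adjusted p = 1.8e-11, adjusted p = 0.15 with an estimated correlation), with the peroxisomal enzyme Ehhadh at log2 8.05 ± 0.81 (n = 3 per group), and all 17 were lower in MLC than in Hepatocyte (median log2 -2.70, camera adjusted p = 7.1e-11, adjusted p = 0.12 with an estimated correlation). Of 21 glycolysis and hypoxia genes 11 were lower and 3 higher in Hepatocyte, also adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.24 with an estimated correlation), with 2 higher without MSC replicate 1 or 2 or Hepatocyte replicate 1 or 3. Pyruvate kinase Pkm fell by 5.72 and hexokinase Hk1 by 4.79 there, and they rose by 5.83 and 4.61 in MLC. The size for Ehhadh against MSC is approximate, with a dim MSC mean of 3.2.

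Of 17 adipogenic markers 7 were higher in Hepatocyte than in MSC, also adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.17 with an estimated correlation), with the fatty acid transporter Cd36 at log2 5.56 ± 0.71 and Dgat2 at 5.36 ± 0.56. Of 20 interferon response genes 5 were higher and 1 lower, or 0 lower without MSC replicate 2 or 3 or Hepatocyte replicate 1, also adjusted over the list alone (camera adjusted p = 0.052), with Irf7 at 2.22 ± 0.35. Of 20 cytokines and chemokines 3 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.73), with 2 higher without any 1 MSC array or Hepatocyte replicate 2. Cxcl9 was higher by 3.43 ± 0.25, and Ptgs2 fell by 5.02 and Csf1 by 4.67. The sizes for Cd36, with a dim MSC mean of 2.37, and Ptgs2, with a dim Hepatocyte mean of 3.59, are approximate. Of 20 cholesterol synthesis genes 3 were higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.68), with 9 lower without Hepatocyte replicate 3.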
